A study of Mus musculus with 16 samples.

How the data were processed

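Bulk RNA-seq of 16 libraries was used: colorectum (4 low and 6 high Neu5Gc) and liver (3 low and 3 high) from 8-week-old male mice. Per the labels, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit. The authors deposited estimated counts per gene and, for the same libraries, TPM, the share of transcripts scaled to a fixed total, each with 36118 Ensembl gene IDs per tissue. The genome build is given by the submitters as GRCm39. The aligner, the quantification tool and the annotation version are not given in the sources used here. The deposited estimated counts are not whole numbers. In a check over 9149 colorectum and 6686 liver genes they equalled TPM times 1 factor per gene and 1 factor per library, with a largest absolute log2 deviation of 1.1e-14 in the colorectum and 9.5e-10 in the liver. They were rounded to whole numbers before the tests. Symbols come from a GRCm38 annotation (GENCODE M21), which named 35825 IDs (99.2%). For 37 IDs the symbol is shared with another ID, and coordinates are not given.

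Groups follow the sample labels, which conflict with the design text of the series (6 control and 4 treated mice). Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit and test, two-sided) and Benjamini-Hochberg adjustment at 0.05. The difference between tissues was the interaction contrast in a fit of all 16 libraries, where only genes passing the filter over the 4 groups were tested. Overlaps between tissues were compared with Fisher's exact test. Of 58 gene lists, those with at least 5 tested members were tested with camera (limma 3.58.1, inter-gene correlation 0.01), and calls were recounted with a correlation estimated per list and with fry. Tests, lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule the text names, per tissue, the 10 largest rises and falls among called genes averaging at least 5 CPM, without predicted or unnamed genes. It also names Apc, Cmah, Alb and Muc2, up to 4 members of each list described, and the 5 genes with the smallest p for the difference between tissues. Some genes that the rule names are not reported here. Chosen after values were seen were the lists that are described, the genes named because they were called in every fit leaving out 1 library, Neu3 in the tissue difference, and the marker sets of kidney, prostate, Paneth cells, further skeletal muscle and the HOX genes.

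Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no robust step, no count filter, fold thresholds, limma on log2(TPM + 1) and log2(TPM + 0.1), that with no TPM filter, all 16 libraries in 1 fit, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were fits without low libraries 3 and 4, with or without high libraries 4 and 5, a liver thinned to 1 depth, and the liver without muscle and clock genes. Same-numbered libraries were checked for shared deviations. Pearson correlations across genes were -0.10, -0.07, -0.03 and -0.06 for the 4 numbers in the colorectum and 0.47, 0.28 and 0.07 in the liver, and between tissues they ran from -0.13 to 0.02. The main fits did not pair samples by number. In the liver, where the correlations were positive, a link between same-numbered libraries cannot be excluded. Genes are not independent replicates in these correlations. A library's own number gave the best match in 0 of 8 colorectum and 4 of 6 liver libraries.

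On simulated counts with 200 genes changed, 56% of 2-fold and 96% of 4-fold changes were recovered in the colorectum (17751 genes tested, 7 false calls), 79% and 98.0% in the liver (15257 genes, 14 false calls), and 20% and 79% for the difference between tissues (18505 genes, 4 false calls).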

Results

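Bulk RNA-seq was analysed for the colorectum and the liver of 8-week-old male mice carrying the Min allele of Apc, a strain that develops intestinal adenomas. The mice drank water with N-glycolylneuraminic acid (Neu5Gc), a sialic acid, for 14 days. The low group, the control, received 0.0127 mg/ml and the high group, the treatment, 0.2535 mg/ml. By its title the series is about Neu5Gc intake and the expression of genes related to colorectal cancer. The sample labels give 4 low and 6 high colorectum libraries and 3 low and 3 high liver libraries. The design text of the series instead states 6 control and 4 treated mice, and groups and directions here follow the sample labels. Were the colorectum group names exchanged, every colorectum direction would turn, and so would whether a gene moved alike or oppositely in the liver. Total estimated counts, in units of 1e6, were 48.3 to 73.9 in the low and 46.1 to 70.7 in the high colorectum libraries. In the liver they were 47.5 to 55.9 in the low and 68.8 to 86.1 in the high libraries, so that depths did not overlap. Values are mean ± SD of counts per 1e6 counts (CPM) over these libraries, and log2 fold changes are high minus low. A bracket after a further gene gives its log2 fold change ± standard error (SE).

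In the colorectum, 2 posterior homeobox genes were among the largest rises with high Neu5Gc, counted over called genes that averaged at least 5 CPM. Hoxd13 (ENSMUSG00000001819), a posterior homeobox gene, rose from 0.744 ± 1.21 to 88.1 ± 20.6 CPM (log2 fold change 6.94, SE 1.05, adjusted p = 0.0031). Hoxb13 (ENSMUSG00000049604), another posterior homeobox gene, rose from 21 ± 28.5 to 438 ± 108 CPM (log2 fold change 4.38, SE 0.86, adjusted p = 0.0102). Atp12a (ENSMUSG00000022229), a proton-potassium pump subunit, rose from 6.42 ± 10.7 to 480.1 ± 313 CPM (log2 fold change 6.23, SE 1.32, adjusted p = 0.0145). Trpv3 (ENSMUSG00000043029), a calcium-permeable channel, rose from 2.35 ± 0.824 to 54.1 ± 12.3 CPM (log2 fold change 4.53, SE 0.27, adjusted p = 1.1e-05). Trpv6 (ENSMUSG00000029868), an epithelial calcium channel, rose from 0.599 ± 0.683 to 12.7 ± 1.84 CPM (log2 fold change 4.43, SE 0.70, adjusted p = 0.00279). St8sia5 (ENSMUSG00000025425), a sialyltransferase, rose from 0.37 ± 0.602 to 13.5 ± 9.15 CPM (log2 fold change 5.23, SE 1.09, adjusted p = 0.0128). Ly6g (ENSMUSG00000022582, 6.32 ± 0.83, adjusted p = 0.00153) and Exosc6 (ENSMUSG00000109941, 5.56 ± 1.38, adjusted p = 0.028) rose. Mettl7a3 (ENSMUSG00000058057, 5.41 ± 0.49, adjusted p = 1.3e-04) and Slc37a2 (ENSMUSG00000032122, 4.57 ± 0.67, adjusted p = 0.00247) rose. For each of these 10 genes every high library lay above every low library. Exosc6 lost its call without low library 2 or high libraries 1, 3, 5 and 6 (adjusted p up to 0.0584, log2 change 13.84 without low library 1).

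Further genes stayed called whichever single library was left out. Tgm3 (ENSMUSG00000027401), a transglutaminase, rose from 54.8 ± 78.4 to 1058 ± 314 CPM (log2 fold change 4.27, SE 0.88, adjusted p = 0.0125). Tmprss13 (ENSMUSG00000037129, 4.16 ± 0.94, adjusted p = 0.0177) and Gjb5 (ENSMUSG00000042357, 4.04 ± 0.49, adjusted p = 5.0e-04) rose. Without low library 3 the rise of Tmprss13 was 6.38. Over 6 posterior homeobox genes the summed CPM was 467 to 813 in the high libraries and 28.9 to 34.2 in low libraries 1, 2 and 4. Low library 3 lay between them at 115.

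Among falls that stayed called whichever single library was left out were those of a bile acid transporter and of a homeobox gene of the middle cluster. Slc51a (ENSMUSG00000035699), a subunit of the basolateral bile acid exporter, fell from 114 ± 70.9 to 0.852 ± 0.57 CPM (log2 fold change -7.08, SE 0.73, adjusted p = 4.3e-04). Osr2 (ENSMUSG00000022330), a zinc finger transcription factor, fell from 57.4 ± 39.5 to 0.603 ± 0.274 CPM (log2 fold change -6.58, SE 0.74, adjusted p = 6.4e-04). Hoxb8 (ENSMUSG00000056648), a homeobox gene, fell from 29.2 ± 17.1 to 0.696 ± 0.162 CPM (log2 fold change -5.39, SE 0.55, adjusted p = 3.2e-04). Nts (ENSMUSG00000019890), which encodes neurotensin, fell from 20.9 ± 13.2 to 0.418 ± 0.278 CPM (log2 fold change -5.63, SE 0.63, adjusted p = 4.4e-04). Prap1 (ENSMUSG00000025467, -5.53 ± 0.80, adjusted p = 0.0023) and ccdc198 (ENSMUSG00000021850, -5.17 ± 0.77, adjusted p = 0.00238) fell. Slc3a1 (ENSMUSG00000024131, -4.81 ± 0.72, adjusted p = 0.00279) and Slc13a1 (ENSMUSG00000029700, -4.70 ± 0.70, adjusted p = 0.00271) fell. Acaa1b (ENSMUSG00000010651, -5.24 ± 0.96, adjusted p = 0.00771) and Ggt1 (ENSMUSG00000006345, -5.44 ± 1.20, adjusted p = 0.0177) fell. Atp6v0a4 (ENSMUSG00000038600, -6.41 ± 1.45, adjusted p = 0.0195) and Tmem229a (ENSMUSG00000048022, -5.46 ± 1.17, adjusted p = 0.0149) fell. Low library 4 held the highest values of Atp6v0a4 (83.0 CPM), Tmem229a (80.4 CPM) and Slc3a1 (226 CPM). Without that library the falls were -2.29 for Atp6v0a4, -2.13 for Tmem229a, -2.71 for Ggt1 and -3.38 for Acaa1b. Of 3 other count-based fits, 1 called Atp6v0a4, 1 called Tmem229a, and 2 each called Ggt1 and Slc3a1. The summed CPM of low library 4 over 16 kidney tubule genes was 15758, against at most 60.8 in any other colorectum library.

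The 10 largest falls, over called genes that averaged at least 5 CPM, were carried by single low libraries. Kidney genes rested on low library 4 and pancreatic enzyme genes on low library 3. Acsm2 (ENSMUSG00000030945, -9.07 ± 2.50, adjusted p = 0.0402) and Slc22a12 (ENSMUSG00000061742, -8.64 ± 2.51, adjusted p = 0.0472) fell. Slc7a13 (ENSMUSG00000041052, -8.53 ± 2.31, adjusted p = 0.0377) and Cpa1 (ENSMUSG00000054446, -8.82 ± 2.49, adjusted p = 0.0433) fell. Prss2 (ENSMUSG00000057163, -8.74 ± 2.34, adjusted p = 0.0366) and Cel (ENSMUSG00000026818, -8.58 ± 2.26, adjusted p = 0.0344) fell. Ctrb1 (ENSMUSG00000031957, -8.25 ± 2.35, adjusted p = 0.0443) and Cela3b (ENSMUSG00000023433, -8.02 ± 2.12, adjusted p = 0.0349) fell. Cpb1 (ENSMUSG00000011463, -7.85 ± 2.09, adjusted p = 0.0357) and Cela2a (ENSMUSG00000058579, -7.84 ± 2.13, adjusted p = 0.038) fell. Low library 3 held a summed CPM of 5768 over 16 pancreatic acinar genes, against 101 to 121 in the other low and 305 to 505 in the high colorectum libraries. By this sum the high libraries lay above the other low ones. Of 13 acinar genes tested, 7 fell (11 adjusted over the list alone). Acinar genes had a camera adjusted p of 0.0904, and adjusted p = 0.797 with an estimated correlation. Acsm2 lost its call without low library 4 or high libraries 1, 2, 3, 4, 5 and 6 (adjusted p up to 0.94, log2 change -0.11 without low library 4). Slc22a12 lost its call without low library 4 or high libraries 2, 3, 4 and 5 (adjusted p up to 0.898, log2 change -0.30 without low library 4). Slc7a13 lost its call without low library 4 or high libraries 2, 3, 4, 5 and 6 (adjusted p up to 0.634, log2 change -0.69 without low library 4). Cpa1 lost its call without low libraries 2 and 3 or high libraries 1, 3, 4 and 6 (adjusted p up to 0.489, log2 change -1.64 without low library 3). Prss2 lost its call without low library 3 or high libraries 1, 3, 4 and 6 (adjusted p up to 0.379, log2 change -1.44 without low library 3). Cel lost its call without low library 3 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.295, log2 change -1.53 without low library 3). Ctrb1 lost its call without low libraries 2 and 3 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.437, log2 change -1.68 without low library 3). Cela3b, Cpb1 and Cela2a lost their calls without low library 3 or high libraries 1, 3, 4, 5 and 6. Their adjusted p went up to 0.411, 0.574 and 0.612, and their log2 changes without low library 3 were -0.85, -0.51 and -0.60.

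**Figure D1:**
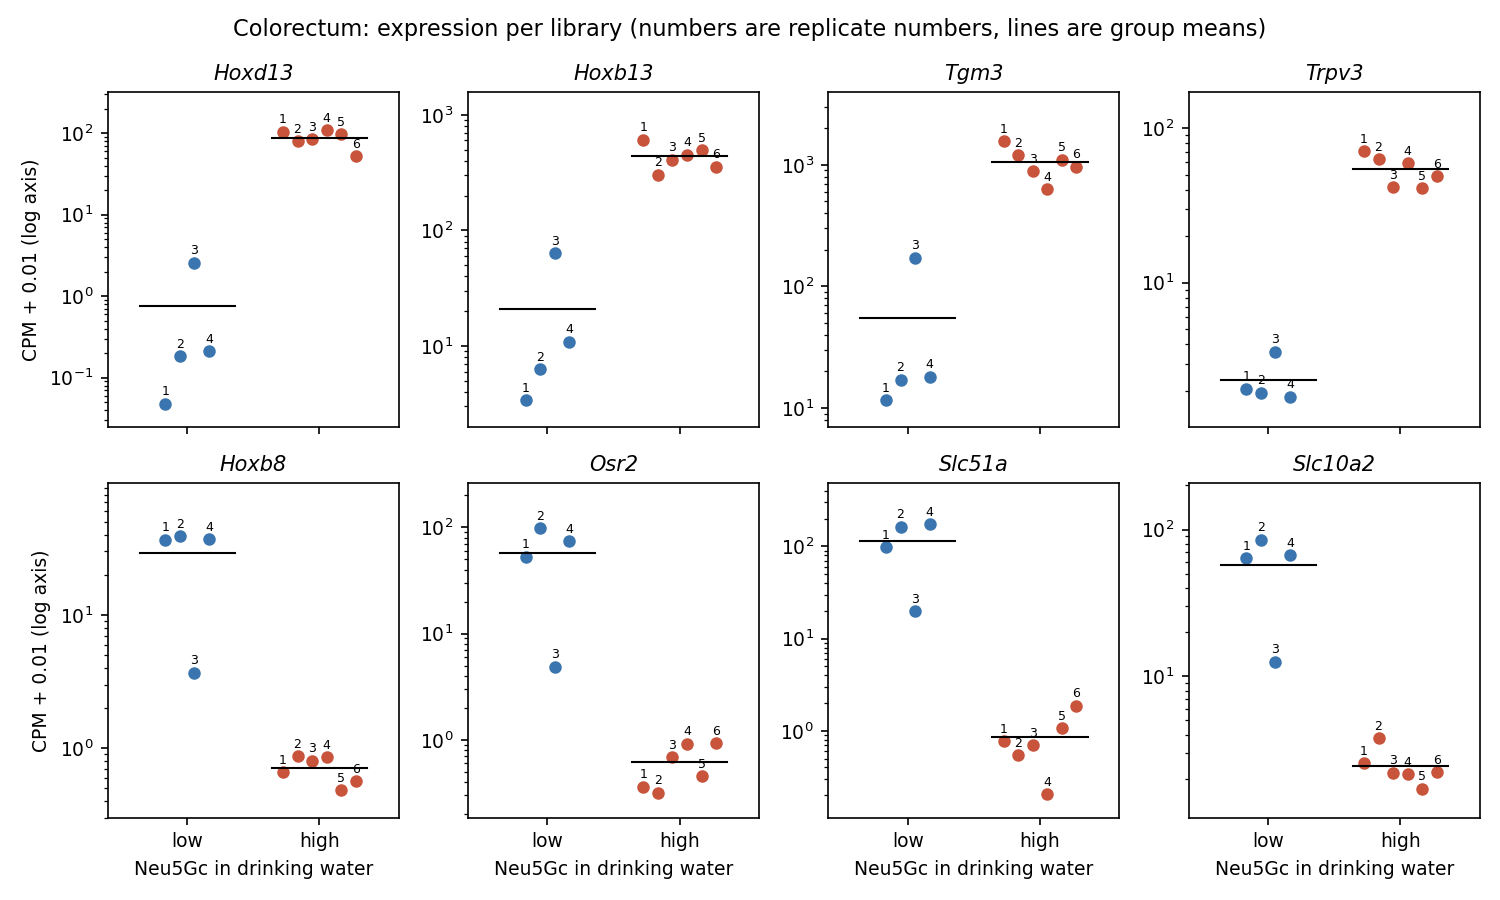
CPM plus 0.01 on a log axis for 8 genes in each colorectum library, low Neu5Gc in blue and high in red, with replicate numbers beside the points and black lines at the group means. Hoxd13, Hoxb13, Tgm3 and Trpv3 are higher in every high library, Hoxb8, Osr2, Slc51a and Slc10a2 are lower, and low library 3 is the low library nearest to the high group.

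**Figure D2:**
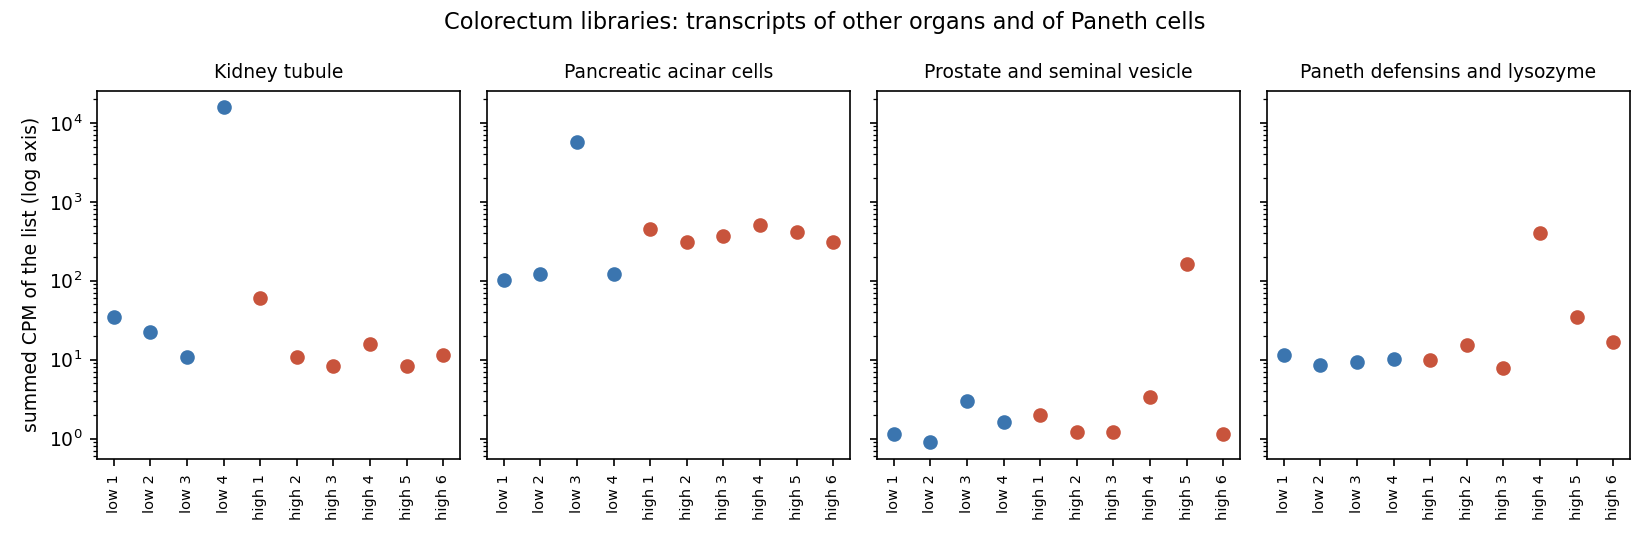
Summed CPM (log axis) of marker genes of kidney tubule, pancreatic acinar cells, prostate and seminal vesicle, and Paneth cells in each colorectum library, low Neu5Gc in blue and high in red. Kidney genes reach 15758 in low library 4, acinar genes 5768 in low library 3, prostate genes 163 in high library 5 and Paneth genes 403 in high library 4.

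By edgeR's quasi-likelihood test, 2784 of 17961 genes tested in the colorectum differed (15.5%), 1309 higher and 1475 lower with high Neu5Gc. Of these, 1209 differed by at least 2-fold (430 higher, 779 lower). The biological coefficient of variation was 35.5%. Values of the groups did not overlap for 2518 genes (14.0%, against 0.952% by chance). A total of 1370 genes (656 higher, 714 lower) were called in every fit that left out 1 library. The count fell to 1849 without low library 2, 1689 without high library 1 and 1592 without high library 5. Without low libraries 3 and 4 it was 2107 (1562 of the 2784).

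The gene mutated in this strain, Apc (ENSMUSG00000005871), went from 100.4 ± 22.8 to 69.7 ± 17.9 CPM in the colorectum and did not pass the test (log2 fold change -0.53, SE 0.20, adjusted p = 0.088), but was called without high library 2 (-0.68, adjusted p = 0.0187). Cmah (ENSMUSG00000016756), the enzyme that makes Neu5Gc, fell from 71.2 ± 19.1 to 21.4 ± 8.07 CPM (log2 fold change -1.74, SE 0.28, adjusted p = 0.00285). Muc2 (ENSMUSG00000025515), the main intestinal mucin, fell from 11235 ± 4434 to 2641 ± 1189 CPM (log2 fold change -2.09, SE 0.33, adjusted p = 0.00238). The albumin gene Alb (ENSMUSG00000029368) went from 219 ± 347 to 33.5 ± 11.1 CPM and did not pass (log2 fold change -2.71, SE 0.86, adjusted p = 0.0612), with 739 CPM in low library 4. Without that library its change was -0.44, and without low library 3 it was called (-3.06, adjusted p = 0.0366). In the liver, Alb went from 59925 ± 8739.9 to 66711 ± 8805 CPM and did not pass (log2 fold change 0.15, SE 0.13, adjusted p = 0.545). There, Alb's sign turned on the TPM scale. Muc2 was too low in the liver to be tested (from 0.11 ± 0.0427 to 0.721 ± 1.07 CPM).

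Genes of the colorectal cancer pathway went both ways. Of 61 colorectal cancer pathway genes, 7 rose and 4 fell (8 rose and 4 fell adjusted over the list alone). The share called was near the 15.5% over all genes. Colorectal cancer pathway genes had a camera adjusted p of 0.131, and adjusted p = 0.797 with an estimated correlation. Tcf7l1 (ENSMUSG00000055799), a T cell factor of the Wnt pathway, rose from 15.6 ± 5.7 to 128 ± 16.8 CPM (log2 fold change 3.04, SE 0.22, adjusted p = 3.3e-05). Map2k1 (ENSMUSG00000004936), a MAP kinase kinase, rose from 135 ± 9.75 to 241 ± 16.5 CPM (log2 fold change 0.83, SE 0.10, adjusted p = 4.3e-04). Rac3 (ENSMUSG00000018012, 0.84 ± 0.24, adjusted p = 0.0388) and Tcf7 (ENSMUSG00000000782, 0.83 ± 0.26, adjusted p = 0.0482) rose. Of 25 Wnt targets and stem cell genes, 3 rose and 3 fell (4 rose and 3 fell adjusted over the list alone). Wnt targets and stem cell genes had a camera adjusted p of 0.569, and adjusted p = 0.9 with an estimated correlation. Ascl2 (ENSMUSG00000009248), a stem cell transcription factor, rose from 5.25 ± 1.24 to 13.3 ± 2.6 CPM (log2 fold change 1.33, SE 0.21, adjusted p = 0.00236). Prom1 (ENSMUSG00000029086, -1.62 ± 0.32, adjusted p = 0.00872) and Cd44 (ENSMUSG00000005087, -1.05 ± 0.23, adjusted p = 0.0137) fell. Rac3 lost its call without low libraries 2, 3 and 4 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.0826). Tcf7 lost its call without low libraries 1, 2 and 4 or high libraries 1, 3, 4 and 5 (adjusted p up to 0.103).

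Some DNA replication genes rose. Of 30 DNA replication genes, 5 rose (8 adjusted over the list alone). The share called in either direction was near the 15.5% over all genes. DNA replication genes had a camera adjusted p of 1.7e-04, and adjusted p = 0.797 with an estimated correlation. Rfc3 (ENSMUSG00000033970, 0.75 ± 0.15, adjusted p = 0.00921) and Rrm2 (ENSMUSG00000020649, 0.69 ± 0.21, adjusted p = 0.0433) rose. Fen1 (ENSMUSG00000024742, 0.63 ± 0.18, adjusted p = 0.0372) and Gins2 (ENSMUSG00000031821, 0.59 ± 0.17, adjusted p = 0.0379) rose. For 26 mitosis genes, of which those with the smallest p are named, the median log2 change was 0.22, and 0.05 without low library 4 and 0.39 without low library 3. The camera adjusted p was 0.0184, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low library 4 or high library 3 (adjusted p up to 0.469). Birc5 (ENSMUSG00000017716, 0.57 ± 0.19, adjusted p = 0.06) and Prc1 (ENSMUSG00000038943, 0.42 ± 0.14, adjusted p = 0.0659) did not pass the test. Aurkb (ENSMUSG00000020897, 0.63 ± 0.22, adjusted p = 0.0707) and Cdc20 (ENSMUSG00000006398, 0.65 ± 0.24, adjusted p = 0.0861) did not pass the test. Without low library 1 Birc5 (adjusted p = 0.0394), Aurkb (0.0268) and Cdc20 (0.048) were called, as were Birc5 without high library 2 (0.0389) and Prc1 without low library 3 (0.0172). Rrm2 lost its call without low libraries 2, 3 and 4 or high libraries 1, 4, 5 and 6 (adjusted p up to 0.0967). Fen1 lost its call without low libraries 2 and 4 or high libraries 1, 4, 5 and 6 (adjusted p up to 0.0897). Gins2 lost its call without low libraries 2, 3 and 4 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.0927).

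Many markers of chemosensory and hormone-producing epithelial cells fell. Of 12 tuft cell markers, 8 fell (10 adjusted over the list alone). Tuft cell markers had a camera adjusted p of 2.0e-05, and adjusted p = 0.515 with an estimated correlation. Dclk1 (ENSMUSG00000027797), a tuft cell kinase, fell from 31.4 ± 13.2 to 12.9 ± 3.38 CPM (log2 fold change -1.29, SE 0.25, adjusted p = 0.00771). Rgs13 (ENSMUSG00000051079, -1.56 ± 0.46, adjusted p = 0.0431) and Pou2f3 (ENSMUSG00000032015, -1.20 ± 0.32, adjusted p = 0.0275) fell. Chat (ENSMUSG00000021919, -1.18 ± 0.31, adjusted p = 0.0285) fell. Of 16 enteroendocrine genes, 1 rose and 8 fell (1 rose and 9 fell adjusted over the list alone). Enteroendocrine genes had a camera adjusted p of 1.3e-04, and adjusted p = 0.797 with an estimated correlation. They included Nts. Sct (ENSMUSG00000038580), which encodes secretin, fell from 19.1 ± 10.3 to 2.99 ± 0.763 CPM (log2 fold change -2.68, SE 0.40, adjusted p = 0.00198). Cck (ENSMUSG00000032532, -1.53 ± 0.39, adjusted p = 0.0254) and Tph1 (ENSMUSG00000040046, -1.29 ± 0.21, adjusted p = 0.0028) fell. Rgs13 lost its call without low libraries 1, 2 and 3 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.115, log2 change -1.03 without low library 3). Pou2f3 lost its call without low libraries 1 and 2 or high libraries 1 and 3 (adjusted p up to 0.0607). Chat lost its call without low libraries 2 and 4 or high libraries 1, 3 and 5 (adjusted p up to 0.0728). Cck lost its call without low libraries 1, 2 and 4 or high libraries 1, 3 and 5 (adjusted p up to 0.0594).

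Goblet cell and colonocyte genes went both ways. Of 16 goblet cell genes, 2 rose and 4 fell (3 rose and 6 fell adjusted over the list alone). Goblet cell genes had a camera adjusted p of 0.0471, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low libraries 1, 2 and 3 or high libraries 1, 2, 3 and 4 (adjusted p up to 0.163). Spdef (ENSMUSG00000024215), a goblet cell transcription factor, fell from 145 ± 17.5 to 61.5 ± 11.5 CPM (log2 fold change -1.23, SE 0.14, adjusted p = 4.3e-04). Fcgbp (ENSMUSG00000047730, 0.88 ± 0.24, adjusted p = 0.0329) rose. Galnt12 (ENSMUSG00000039774, -0.997 ± 0.13, adjusted p = 6.2e-04) fell. Of 20 genes of absorptive colonocytes, 7 rose and 5 fell (9 rose and 6 fell adjusted over the list alone). Genes of absorptive colonocytes had a camera adjusted p of 0.329, and adjusted p = 0.797 with an estimated correlation. Besides Slc37a2, Saa1 (ENSMUSG00000074115, 3.29 ± 0.73, adjusted p = 0.0164) and Aqp8 (ENSMUSG00000030762, 2.05 ± 0.32, adjusted p = 0.00236) rose. Car1 (ENSMUSG00000027556), a carbonic anhydrase, fell from 4389 ± 1949 to 449 ± 194 CPM (log2 fold change -3.29, SE 0.40, adjusted p = 5.6e-04). Fcgbp lost its call without low libraries 1, 2 and 4 or high libraries 1 and 6 (adjusted p up to 0.0747).

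More genes of nutrient and bile acid handling fell than rose. Of 19 small intestinal enterocyte genes, 5 fell (1 rose and 11 fell adjusted over the list alone). Small intestinal enterocyte genes had a camera adjusted p of 0.00287, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low library 4 (adjusted p up to 0.127). Sis (ENSMUSG00000027790), a disaccharidase, fell from 6.9 ± 5.28 to 0.178 ± 0.0926 CPM (log2 fold change -5.29, SE 0.68, adjusted p = 7.7e-04). Alpi (ENSMUSG00000079440, -3.92 ± 0.49, adjusted p = 7.5e-04) and Enpep (ENSMUSG00000028024, -2.44 ± 0.33, adjusted p = 0.00108) fell. Slc2a2 (ENSMUSG00000027690, -5.51 ± 1.57, adjusted p = 0.044) fell. Of 21 bile acid genes, 2 rose and 5 fell (2 rose and 8 fell adjusted over the list alone). Bile acid genes had a camera adjusted p of 0.00831, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low library 4 (adjusted p up to 0.254). Slc10a2 (ENSMUSG00000023073), the ileal bile acid uptake transporter, fell from 57.2 ± 31.2 to 2.43 ± 0.708 CPM (log2 fold change -4.55, SE 0.45, adjusted p = 2.7e-04). Slco1a1 (ENSMUSG00000041698, -6.88 ± 1.82, adjusted p = 0.0352) and Akr1d1 (ENSMUSG00000038641, -5.10 ± 1.33, adjusted p = 0.0319) fell. Low library 4, with its kidney transcripts, held the highest values of Slc2a2 (89.5 CPM) and Slco1a1 (96.6 CPM). Slc2a2 and Slco1a1 lost their calls without low library 4 or any single high library (adjusted p up to 0.994 and 0.414). Without low library 4 their log2 changes were -0.01 and -0.62. Akr1d1 lost its call without low library 4 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.132, log2 change -1.55 without low library 4).

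The same held for lipid oxidation and detoxification genes. Of 25 PPAR-alpha targets and fatty acid oxidation genes, 1 rose and 7 fell (1 rose and 13 fell adjusted over the list alone). PPAR-alpha targets and fatty acid oxidation genes had a camera adjusted p of 1.7e-04, and adjusted p = 0.797 with an estimated correlation. Vnn1 (ENSMUSG00000037440), a pantetheinase, fell from 15.6 ± 13.7 to 0.736 ± 0.163 CPM (log2 fold change -4.40, SE 0.48, adjusted p = 3.7e-04). Ppara (ENSMUSG00000022383, -1.78 ± 0.33, adjusted p = 0.006) fell. Of 25 xenobiotic metabolism genes, 2 rose and 8 fell (2 rose and 15 fell adjusted over the list alone). Xenobiotic metabolism genes had a camera adjusted p of 1.1e-04, and adjusted p = 0.797 with an estimated correlation. The list median of -2.51 was -0.92 without low libraries 3 and 4, and that of PPAR-alpha targets went from -0.61 to -0.38. Both lists stayed called. Cyp2c65 (ENSMUSG00000067231), a cytochrome P450, fell from 187 ± 35.7 to 11.2 ± 8.41 CPM (log2 fold change -4.06, SE 0.50, adjusted p = 9.6e-04). Cyp2c55 (ENSMUSG00000025002, -3.08 ± 0.41, adjusted p = 0.00107) and Gsta2 (ENSMUSG00000057933, -5.47 ± 1.57, adjusted p = 0.0449) fell. Cyp3a11 (ENSMUSG00000056035, -2.85 ± 0.80, adjusted p = 0.0376) fell. Gsta2 and Cyp3a11 lost their calls without low library 4 or any single high library (adjusted p up to 0.596 and 0.16). Without low library 4 their log2 changes were -0.57 and -0.95.

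Some B cell and antigen presentation genes rose. Of 16 B cell genes, 6 rose (6 adjusted over the list alone). B cell genes had a camera adjusted p of 2.1e-07, and adjusted p = 0.797 with an estimated correlation. Cd79a (ENSMUSG00000003379), a subunit of the B cell receptor, rose from 4.78 ± 2.8 to 24 ± 6.58 CPM (log2 fold change 2.33, SE 0.35, adjusted p = 0.00192). Blk (ENSMUSG00000014453, 2.46 ± 0.51, adjusted p = 0.0097) and Cd37 (ENSMUSG00000030798, 1.84 ± 0.30, adjusted p = 0.00286) rose. Of 11 MHC class II genes, 6 rose (11 adjusted over the list alone). MHC class II genes had a camera adjusted p of 2.3e-06, and adjusted p = 0.797 with an estimated correlation. H2-Ob (ENSMUSG00000041538, 1.77 ± 0.36, adjusted p = 0.00963) and H2-DMb2 (ENSMUSG00000037548, 1.67 ± 0.34, adjusted p = 0.00883) rose. H2-DMb1 (ENSMUSG00000079547, 1.05 ± 0.22, adjusted p = 0.0104) and Ciita (ENSMUSG00000022504, 0.95 ± 0.26, adjusted p = 0.0315) rose. Of 14 MHC class I genes, 4 rose (5 adjusted over the list alone). MHC class I genes had a camera adjusted p of 0.0138, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low library 3 (adjusted p up to 0.142). Psmb8 (ENSMUSG00000024338, 1.04 ± 0.25, adjusted p = 0.0198) and Psmb9 (ENSMUSG00000096727, 1.002 ± 0.30, adjusted p = 0.0444) rose. H2-Q7 (ENSMUSG00000060550, 0.97 ± 0.24, adjusted p = 0.0215) and Nlrc5 (ENSMUSG00000074151, 0.81 ± 0.23, adjusted p = 0.0353) rose. Ciita lost its call without low libraries 1, 2 and 4 or high libraries 1 and 5 (adjusted p up to 0.0694). Psmb9 lost its call without low libraries 1, 2, 3 and 4 or high libraries 1, 3, 5 and 6 (adjusted p up to 0.0967). H2-Q7 lost its call without low library 2 (adjusted p up to 0.0525). Nlrc5 lost its call without low libraries 2, 3 and 4 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.0797).

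Some cytokine genes rose, while more interferon genes fell than rose. Of 25 cytokine, chemokine and NF-kB genes, 6 rose (7 adjusted over the list alone). Cytokine, chemokine and NF-kB genes had a camera adjusted p of 5.7e-05, and adjusted p = 0.797 with an estimated correlation. Ccl20 (ENSMUSG00000026166), a chemokine, rose from 0.954 ± 0.419 to 6.36 ± 3.51 CPM (log2 fold change 2.74, SE 0.47, adjusted p = 0.00372). Il18 (ENSMUSG00000039217, 1.78 ± 0.31, adjusted p = 0.00464) and Tnf (ENSMUSG00000024401, 2.15 ± 0.54, adjusted p = 0.0229) rose. Duoxa2 (ENSMUSG00000027225, 1.92 ± 0.44, adjusted p = 0.0179) rose. High library 4, with 403 CPM of Paneth cell genes, also held the highest Tnf value, 14.1 CPM. Of 28 interferon response genes, 1 rose and 5 fell (1 rose and 6 fell adjusted over the list alone). Interferon response genes had a camera adjusted p of 0.0184, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low library 1 or high library 2 (adjusted p up to 0.39). Ifit1 (ENSMUSG00000034459), an antiviral protein, fell from 56.6 ± 26.5 to 12.8 ± 8.08 CPM (log2 fold change -2.15, SE 0.49, adjusted p = 0.0182). Gbp2 (ENSMUSG00000028270, 1.49 ± 0.38, adjusted p = 0.0264) rose. Rsad2 (ENSMUSG00000020641, -1.67 ± 0.35, adjusted p = 0.0113) and Ifit3 (ENSMUSG00000074896, -1.34 ± 0.35, adjusted p = 0.0263) fell. Tnf lost its call without low library 2 (adjusted p up to 0.0526). Ifit3 lost its call without low library 1 or high libraries 3, 5 and 6 (adjusted p up to 0.07, log2 change -0.87 without low library 1). Gbp2 lost its call without low libraries 1, 2 and 4 (adjusted p up to 0.0641).

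Genes of sialic acid metabolism went both ways, and their median of 0.04 turned negative on the TPM scale. Of 17 sialic acid genes, 4 rose and 1 fell (5 rose and 3 fell adjusted over the list alone). Sialic acid genes had a camera adjusted p of 0.371, and adjusted p = 0.797 with an estimated correlation. Neu3 (ENSMUSG00000035239), the plasma membrane sialidase, rose from 2.77 ± 0.864 to 11.8 ± 2.63 CPM (log2 fold change 2.08, SE 0.25, adjusted p = 4.3e-04). Casd1 (ENSMUSG00000015189, 0.79 ± 0.15, adjusted p = 0.00664) and Cmas (ENSMUSG00000030282, 0.49 ± 0.11, adjusted p = 0.0161) rose. Of 20 sialyltransferase genes, 3 rose and 2 fell (5 rose and 6 fell adjusted over the list alone). Sialyltransferase genes had a camera adjusted p of 0.569, and adjusted p = 0.797 with an estimated correlation. Besides St8sia5, St6galnac4 (ENSMUSG00000079442, 1.51 ± 0.31, adjusted p = 0.00969) rose. St3gal5 (ENSMUSG00000056091, -1.38 ± 0.25, adjusted p = 0.00478) and St3gal1 (ENSMUSG00000013846, -1.29 ± 0.23, adjusted p = 0.00495) fell.

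Many ribosomal protein genes rose and some mitochondrially encoded genes fell. Of 82 ribosomal protein genes, 42 rose (63 adjusted over the list alone). Ribosomal protein genes had a camera adjusted p of 3.5e-19, and adjusted p = 0.797 with an estimated correlation. Rps19 (ENSMUSG00000040952), of the small subunit, rose from 447 ± 44.1 to 762 ± 107 CPM (log2 fold change 0.77, SE 0.14, adjusted p = 0.00445). Rps28 (ENSMUSG00000067288, 0.87 ± 0.27, adjusted p = 0.04997) and Rpl12 (ENSMUSG00000038900, 0.81 ± 0.18, adjusted p = 0.0141) rose. Rpl27a (ENSMUSG00000046364, 0.73 ± 0.21, adjusted p = 0.0384) rose. Of 13 mitochondrially encoded genes, 3 fell (11 adjusted over the list alone). Mitochondrially encoded genes had a camera adjusted p of 3.1e-04, and adjusted p = 0.797 with an estimated correlation. mt-Nd5 (ENSMUSG00000064367, -1.56 ± 0.44, adjusted p = 0.0361) and mt-Nd4l (ENSMUSG00000065947, -1.53 ± 0.45, adjusted p = 0.0437) fell. mt-Nd2 (ENSMUSG00000064345, -1.24 ± 0.37, adjusted p = 0.044) fell. The list median of -0.97 was -0.41 without low library 3. Without low libraries 3 and 4, a choice made after the data were seen, it was -0.21 and the camera call was lost (adjusted p = 0.263), and the changes of mt-Nd5, mt-Nd4l and mt-Nd2 were -0.33, -0.21 and -0.19. Mitochondrial transcripts made up 12.9% of counts in low library 3 and 2.79% to 6.49% in the other colorectum libraries. Rps28 lost its call without low libraries 1, 2 and 4 or high libraries 1, 2, 3, 4, 5 and 6 (adjusted p up to 0.096). Rpl27a lost its call without low libraries 1 and 4 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.0779). mt-Nd5 lost its call without low library 3 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.078, log2 change -0.72 without low library 3). mt-Nd4l lost its call without low libraries 3 and 4 or high libraries 1, 3, 4, 5 and 6 (adjusted p up to 0.0947, log2 change -0.75 without low library 3). mt-Nd2 lost its call without low libraries 3 and 4 or high libraries 1, 2, 3, 4, 5 and 6 (adjusted p up to 0.105, log2 change -0.67 without low library 3).

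Some vessel and muscle layer genes fell. Of 14 endothelial genes, 4 fell (5 adjusted over the list alone). Endothelial genes had a camera adjusted p of 0.0109, and adjusted p = 0.797 with an estimated correlation. Flt1 (ENSMUSG00000029648, -0.71 ± 0.15, adjusted p = 0.0108) and Tek (ENSMUSG00000006386, -0.70 ± 0.16, adjusted p = 0.0132) fell. Kdr (ENSMUSG00000062960, -0.69 ± 0.15, adjusted p = 0.0126) and Eng (ENSMUSG00000026814, -0.52 ± 0.13, adjusted p = 0.0252) fell. Of 16 smooth muscle genes, 2 fell (2 adjusted over the list alone). That was below the 15.5% called over all genes. Smooth muscle genes had a camera adjusted p of 0.0329, and adjusted p = 0.797 with an estimated correlation. That camera call was lost without low libraries 1, 2 and 3 or high libraries 1, 2 and 5 (adjusted p up to 0.133). Myocd (ENSMUSG00000020542, -1.25 ± 0.33, adjusted p = 0.0269) and Mylk (ENSMUSG00000022836, -0.95 ± 0.15, adjusted p = 0.00254) fell. Eng lost its call without low library 4 or high libraries 1 and 6 (adjusted p up to 0.0575). Myocd lost its call without low library 2 or high libraries 3 and 5 (adjusted p up to 0.0664).

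Over all 58 lists, camera called 31 in the colorectum, 14 higher and 17 lower. With a correlation estimated for each list it called 0, with 2 lists at an unadjusted p under 0.05. The fry test called 6 lists in 1 direction and 39 in either. Of 100 splits of the 10 libraries into groups of 4 and 6, the real one included, 33 called as many lists, and the highest other count was 35.

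**Figure D3:**
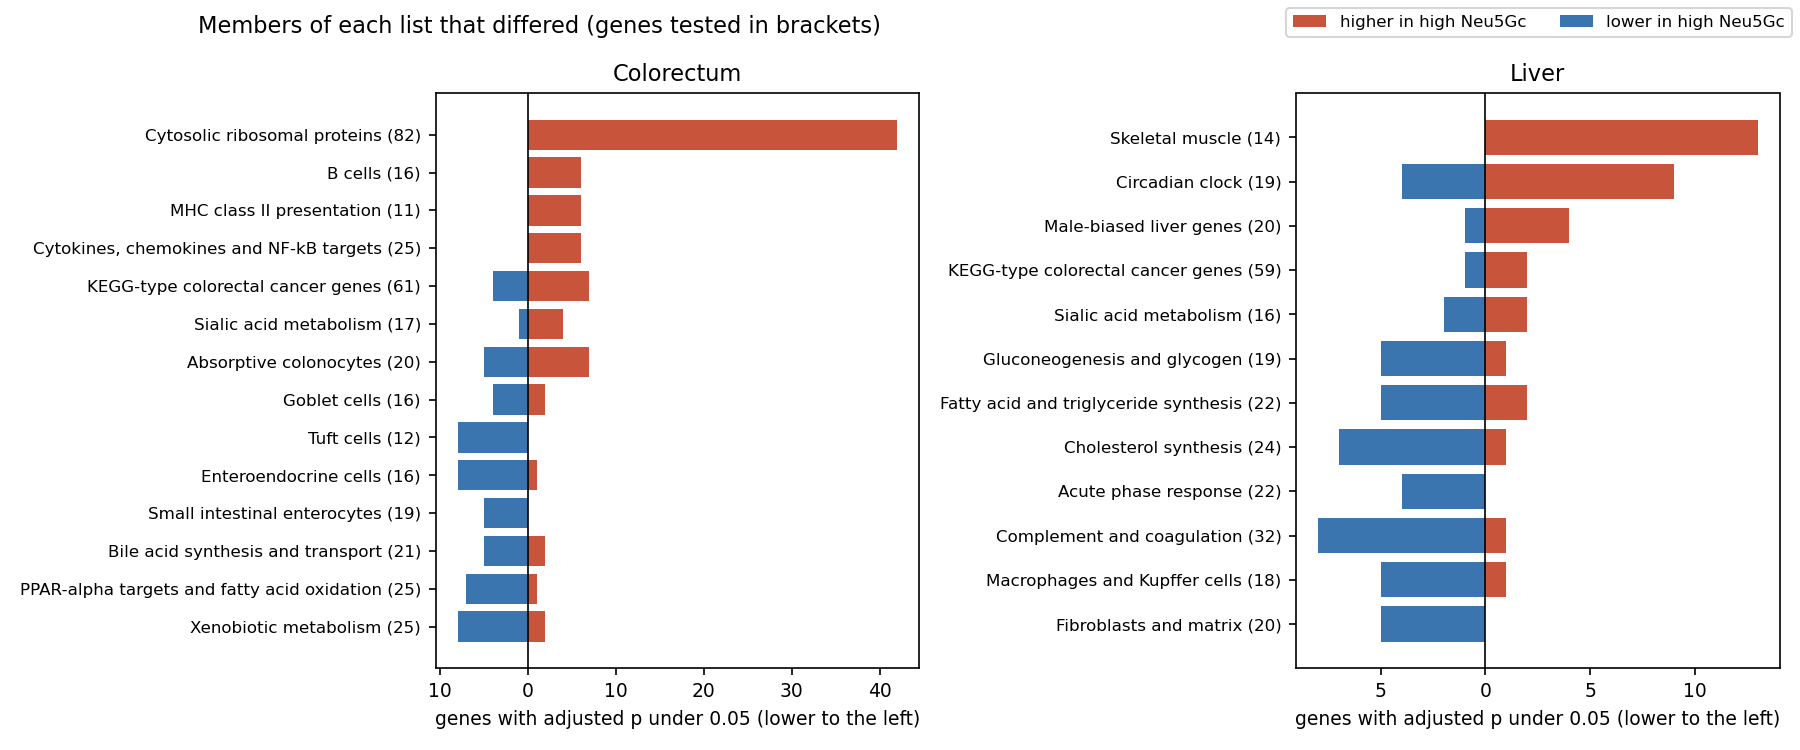
Number of genes per list with an adjusted p under 0.05 in the colorectum and the liver, with genes higher with high Neu5Gc to the right in red and lower ones to the left in blue, and the number tested in brackets. Of the ribosomal protein genes 42 of 82 are higher in the colorectum, and of the skeletal muscle genes 13 of 14 in the liver.

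In the liver, clock and skeletal muscle genes were among the largest rises with high Neu5Gc. Dbp (ENSMUSG00000059824), a clock output gene, rose from 0.824 ± 0.255 to 67.3 ± 23.3 CPM (log2 fold change 6.34, SE 0.36, adjusted p = 3.5e-04). Bhlhe41 (ENSMUSG00000030256), a clock repressor, rose from 0.186 ± 0.0504 to 4.53 ± 1.42 CPM (log2 fold change 4.59, SE 0.34, adjusted p = 1.5e-04). Arntl (ENSMUSG00000055116), a clock activator, fell from 30.2 ± 1.54 to 4.22 ± 1.88 CPM (log2 fold change -2.84, SE 0.30, adjusted p = 0.00226). Npas2 (ENSMUSG00000026077), its partner, fell from 7.89 ± 0.962 to 0.452 ± 0.268 CPM (log2 fold change -4.12, SE 0.35, adjusted p = 5.0e-04). Of 19 clock genes, 9 rose and 4 fell (11 rose and 5 fell adjusted over the list alone). Clock genes had a camera adjusted p of 0.00358, and adjusted p = 0.446 with an estimated correlation. Nr1d2 (ENSMUSG00000021775, 2.89 ± 0.22, adjusted p = 3.7e-04) and Tef (ENSMUSG00000022389, 2.82 ± 0.34, adjusted p = 0.00637) rose. Per3 (ENSMUSG00000028957, 3.37 ± 0.43, adjusted p = 0.0103) rose. Cry1 (ENSMUSG00000020038, -1.78 ± 0.23, adjusted p = 0.00304) fell. Per3 lost its call without low library 3 (adjusted p up to 0.0825).

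Contractile and energy genes of skeletal muscle rose in the high liver libraries. Of 14 skeletal muscle genes tested in the liver, 13 rose (14 adjusted over the list alone). Skeletal muscle genes had a camera adjusted p of 1.2e-20, and adjusted p = 0.433 with an estimated correlation. Their median log2 change was 5.13. Myh2 (ENSMUSG00000033196), a myosin, rose from 0.245 ± 0.38 to 18.6 ± 2.39 CPM (log2 fold change 6.22, SE 0.89, adjusted p = 0.0255). Mb (ENSMUSG00000018893), myoglobin, rose from 0.374 ± 0.476 to 25.8 ± 4.4 CPM (log2 fold change 6.10, SE 0.76, adjusted p = 0.0173). Atp2a1 (ENSMUSG00000030730, 5.24 ± 0.46, adjusted p = 0.00207) and Tnnc2 (ENSMUSG00000017300, 5.40 ± 0.52, adjusted p = 0.00253) rose. Acta1 (ENSMUSG00000031972, 5.74 ± 0.92, adjusted p = 0.0402) and Myh1 (ENSMUSG00000056328, 5.28 ± 0.75, adjusted p = 0.0255) rose. Tnnt3 (ENSMUSG00000061723, 5.23 ± 0.92, adjusted p = 0.0481) and Ckm (ENSMUSG00000030399, 5.02 ± 0.86, adjusted p = 0.0461) rose. Myl1 (ENSMUSG00000061816, 4.93 ± 0.52, adjusted p = 0.00326) rose. Called whichever library was left out, Mylpf (ENSMUSG00000030672, 3.42 ± 0.27, adjusted p = 2.6e-04) and Tpm2 (ENSMUSG00000028464, 2.04 ± 0.21, adjusted p = 9.3e-04) rose. The summed CPM of the 13 called genes was 216 to 308 in the high and 2.55 to 14.8 in the low liver libraries, at most 0.0308% of counts. Myh2 lost its call without low libraries 2 and 3 or high libraries 1, 2 and 3 (adjusted p up to 0.131). Mb lost its call without low library 2 or high libraries 1 and 2 (adjusted p up to 0.0927). Acta1 lost its call without low library 2 or high libraries 1, 2 and 3 (adjusted p up to 0.141). Myh1 lost its call without low libraries 1 and 3 or high libraries 1 and 2 (adjusted p up to 0.143). Tnnt3 lost its call without low libraries 1 and 2 or high libraries 1, 2 and 3 (adjusted p up to 0.17). Ckm lost its call without low library 2 or high libraries 1, 2 and 3 (adjusted p up to 0.156).

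**Figure D4:**
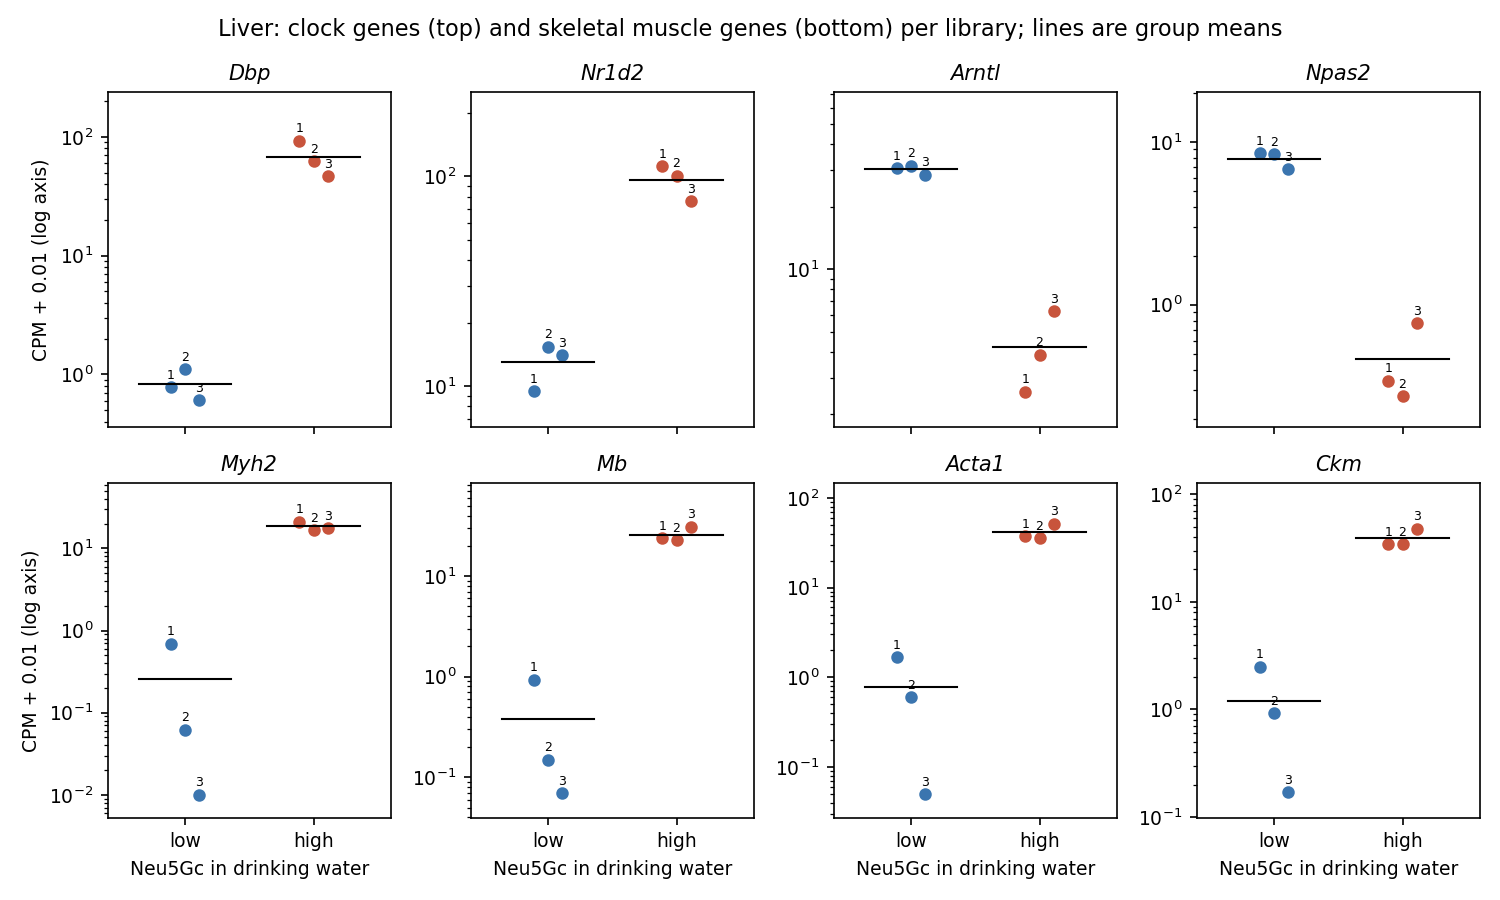
CPM plus 0.01 on a log axis for 4 clock genes and 4 skeletal muscle genes in each liver library, low Neu5Gc in blue and high in red, with replicate numbers beside the points and black lines at the group means. Dbp, Nr1d2 and the muscle genes are higher, and Arntl and Npas2 lower, in each of the 3 high libraries.

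Arntl was among the largest liver falls over called genes that averaged at least 5 CPM, beside genes of varied function. Loxl4 (ENSMUSG00000025185), a lysyl oxidase, fell from 15.7 ± 4.4 to 1.47 ± 0.43 CPM (log2 fold change -3.42, SE 0.28, adjusted p = 4.9e-04). Igfbp1 (ENSMUSG00000020429), which binds insulin-like growth factors, fell from 86.9 ± 7.13 to 12.1 ± 2.35 CPM (log2 fold change -2.84, SE 0.15, adjusted p = 2.4e-05). Ppard (ENSMUSG00000002250), a nuclear receptor, fell from 41.8 ± 3.65 to 6.03 ± 0.723 CPM (log2 fold change -2.79, SE 0.13, adjusted p = 2.0e-05). Clic3 (ENSMUSG00000015093, -3.04 ± 0.38, adjusted p = 0.00716) and Cdkn1a (ENSMUSG00000023067, -2.75 ± 0.22, adjusted p = 2.6e-04) fell. Tubb2a (ENSMUSG00000058672, -2.26 ± 0.16, adjusted p = 1.4e-04) and Chka (ENSMUSG00000024843, -2.25 ± 0.16, adjusted p = 1.2e-04) fell. Elovl3 (ENSMUSG00000038754, -2.09 ± 0.32, adjusted p = 0.0179) fell. Called whichever library was left out, Pitpnm1 (ENSMUSG00000024851, -1.79 ± 0.14, adjusted p = 2.1e-04) fell. Of that kind too, Clec2h (ENSMUSG00000030364, 2.61 ± 0.12, adjusted p = 2.0e-05) and Slc25a4 (ENSMUSG00000031633, 1.68 ± 0.14, adjusted p = 3.7e-04) rose. Upp2 (ENSMUSG00000026839, 1.57 ± 0.19, adjusted p = 0.00236) rose. Elovl3 lost its call without low library 3 or high library 2 (adjusted p up to 0.101).

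More genes of glucose and fatty acid metabolism fell than rose. Of 19 gluconeogenesis and glycogen genes, 1 rose and 5 fell (3 rose and 10 fell adjusted over the list alone). Gluconeogenesis and glycogen genes had a camera adjusted p of 0.00226, and adjusted p = 0.433 with an estimated correlation. Irs2 (ENSMUSG00000038894), an insulin receptor substrate, fell from 28.7 ± 3.06 to 9.21 ± 0.775 CPM (log2 fold change -1.64, SE 0.12, adjusted p = 1.7e-04). Ppp1r3c (ENSMUSG00000067279, -1.30 ± 0.20, adjusted p = 0.00765) and Got1 (ENSMUSG00000025190, -0.97 ± 0.14, adjusted p = 0.00487) fell. Of 22 fatty acid and triglyceride genes, 2 rose and 5 fell (3 rose and 6 fell adjusted over the list alone). Fatty acid and triglyceride genes had a camera adjusted p of 0.0143, and adjusted p = 0.55 with an estimated correlation. That camera call was lost without high library 3 (adjusted p up to 0.0959). Acly (ENSMUSG00000020917), which makes cytosolic acetyl-CoA, fell from 349 ± 32.7 to 176 ± 6.5 CPM (log2 fold change -0.99, SE 0.10, adjusted p = 0.00104). Pnpla3 (ENSMUSG00000041653, -2.72 ± 0.33, adjusted p = 0.00196) and Acacb (ENSMUSG00000042010, -1.38 ± 0.19, adjusted p = 0.00408) fell. Elovl5 (ENSMUSG00000032349, -1.21 ± 0.14, adjusted p = 0.00131) fell.

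More cholesterol synthesis genes fell than rose, and bile acid genes went both ways. Of 24 cholesterol synthesis genes, 1 rose and 7 fell (1 rose and 9 fell adjusted over the list alone). Cholesterol synthesis genes had a camera adjusted p of 0.00226, and adjusted p = 0.433 with an estimated correlation. Pmvk (ENSMUSG00000027952), a mevalonate pathway kinase, fell from 52.5 ± 0.941 to 25.8 ± 3.84 CPM (log2 fold change -1.02, SE 0.12, adjusted p = 0.00145). Lss (ENSMUSG00000033105, -0.76 ± 0.11, adjusted p = 0.00408) and Mvd (ENSMUSG00000006517, -0.74 ± 0.13, adjusted p = 0.0127) fell. Fdps (ENSMUSG00000059743, -0.56 ± 0.14, adjusted p = 0.0438) fell. Of 24 bile acid genes, 4 rose and 5 fell (5 rose and 7 fell adjusted over the list alone). Bile acid genes had a camera adjusted p of 0.841, and adjusted p = 0.887 with an estimated correlation. Slco1b2 (ENSMUSG00000030236), an uptake carrier, rose from 790.0 ± 46.8 to 1456 ± 198 CPM (log2 fold change 0.88, SE 0.11, adjusted p = 0.00189). Abcg5 (ENSMUSG00000040505, 0.65 ± 0.12, adjusted p = 0.015) rose. Cyp8b1 (ENSMUSG00000050445, -0.79 ± 0.15, adjusted p = 0.015) and Nr0b2 (ENSMUSG00000037583, -0.65 ± 0.15, adjusted p = 0.0322) fell. Mvd lost its call without low library 3 or high library 2 (adjusted p up to 0.0702). Fdps lost its call without low libraries 1 and 3 or high libraries 1 and 2 (adjusted p up to 0.174). Abcg5 lost its call without low library 3 (adjusted p up to 0.0731). Cyp8b1 lost its call without low library 1 or high library 2 (adjusted p up to 0.0633). Nr0b2 lost its call without low libraries 1, 2 and 3 or high libraries 1 and 3 (adjusted p up to 0.128).

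Some plasma protein genes fell. Of 32 complement and coagulation genes, 1 rose and 8 fell (1 rose and 13 fell adjusted over the list alone). Complement and coagulation genes had a camera adjusted p of 0.0141, and adjusted p = 0.433 with an estimated correlation. C3 (ENSMUSG00000024164), the central complement component, fell from 7587 ± 192 to 4440.3 ± 115 CPM (log2 fold change -0.77, SE 0.06, adjusted p = 1.5e-04). C5ar1 (ENSMUSG00000049130, -1.34 ± 0.32, adjusted p = 0.0376) and Fga (ENSMUSG00000028001, -0.64 ± 0.11, adjusted p = 0.0142) fell. F10 (ENSMUSG00000031444, -0.49 ± 0.11, adjusted p = 0.0264) fell. Of 22 acute phase genes, 4 fell (10 adjusted over the list alone). Acute phase genes had a camera adjusted p of 0.00467, and adjusted p = 0.548 with an estimated correlation. Itih3 (ENSMUSG00000006522, -0.92 ± 0.10, adjusted p = 0.00108) and Serpina3n (ENSMUSG00000021091, -0.65 ± 0.12, adjusted p = 0.0157) fell. Lbp (ENSMUSG00000016024, -0.63 ± 0.13, adjusted p = 0.0224) and Hp (ENSMUSG00000031722, -0.62 ± 0.11, adjusted p = 0.0116) fell. C5ar1 lost its call without low libraries 2 and 3 or high libraries 2 and 3 (adjusted p up to 0.145). Fga lost its call without low library 1 or high libraries 1 and 2 (adjusted p up to 0.0623). F10 lost its call without low libraries 1 and 3 or high libraries 1 and 2 (adjusted p up to 0.119). Serpina3n lost its call without low library 3 or high library 2 (adjusted p up to 0.0615). Lbp lost its call without low library 3 or high libraries 1 and 2 (adjusted p up to 0.101). Hp lost its call without low library 3 (adjusted p up to 0.0535).

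Some macrophage and cytokine genes fell. Of 18 macrophage and Kupffer cell genes, 1 rose and 5 fell (1 rose and 9 fell adjusted over the list alone). Macrophage and Kupffer cell genes had a camera adjusted p of 2.3e-04, and adjusted p = 0.446 with an estimated correlation. Adgre1 (ENSMUSG00000004730, -0.69 ± 0.14, adjusted p = 0.0198) and Csf1r (ENSMUSG00000024621, -0.67 ± 0.17, adjusted p = 0.049) fell. Cd68 (ENSMUSG00000018774, -0.57 ± 0.12, adjusted p = 0.027) fell. Of 18 cytokine, chemokine and NF-kB genes, 2 fell (2 adjusted over the list alone). Cytokine, chemokine and NF-kB genes had a camera adjusted p of 0.00226, and adjusted p = 0.433 with an estimated correlation. Ccl2 (ENSMUSG00000035385, -1.60 ± 0.33, adjusted p = 0.0221) and Il1b (ENSMUSG00000027398, -1.32 ± 0.22, adjusted p = 0.00842) fell. Adgre1 lost its call without low libraries 2 and 3 or high library 2 (adjusted p up to 0.0983). Csf1r lost its call without low libraries 1, 2 and 3 or high libraries 2 and 3 (adjusted p up to 0.173). Cd68 lost its call without low libraries 1, 2 and 3 or high libraries 1, 2 and 3 (adjusted p up to 0.12). Ccl2 lost its call without low library 3 or high libraries 1 and 2 (adjusted p up to 0.0909).

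Some matrix and stellate cell genes fell. Of 20 fibroblast and matrix genes, 5 fell (1 rose and 11 fell adjusted over the list alone). Fibroblast and matrix genes had a camera adjusted p of 1.3e-04, and adjusted p = 0.433 with an estimated correlation. Pdgfra (ENSMUSG00000029231, -0.81 ± 0.18, adjusted p = 0.0322) and Col5a1 (ENSMUSG00000026837, -0.60 ± 0.14, adjusted p = 0.035) fell. Col6a1 (ENSMUSG00000001119, -0.53 ± 0.12, adjusted p = 0.0358) and Col3a1 (ENSMUSG00000026043, -0.51 ± 0.12, adjusted p = 0.0405) fell. Of 15 stellate cell and cholangiocyte genes, 1 rose and 5 fell (1 rose and 7 fell adjusted over the list alone). Stellate cell and cholangiocyte genes had a camera adjusted p of 5.6e-04, and adjusted p = 0.433 with an estimated correlation. Krt19 (ENSMUSG00000020911), a bile duct keratin, fell from 4.18 ± 0.0869 to 1.17 ± 0.272 CPM (log2 fold change -1.84, SE 0.21, adjusted p = 0.00131). Des (ENSMUSG00000026208, 1.05 ± 0.22, adjusted p = 0.0252), also listed among smooth muscle genes, rose. It did so in the libraries where skeletal muscle genes rose, and the cells behind its rise were not tested. Lrat (ENSMUSG00000028003, -0.81 ± 0.20, adjusted p = 0.046) and Reln (ENSMUSG00000042453, -0.77 ± 0.13, adjusted p = 0.00885) fell. For 14 endothelial genes the median log2 change was -0.31. Their camera adjusted p was 3.7e-04, and adjusted p = 0.433 with an estimated correlation. Eng (-0.31 ± 0.09, adjusted p = 0.0618) and Pecam1 (ENSMUSG00000020717, -0.42 ± 0.12, adjusted p = 0.0625) did not pass the test. Pdgfra lost its call without low libraries 1, 2 and 3 or high libraries 2 and 3 (adjusted p up to 0.133). Col5a1 lost its call without low libraries 1, 2 and 3 or high libraries 1 and 2 (adjusted p up to 0.159). Col6a1 lost its call without low libraries 1, 2 and 3 or high libraries 1, 2 and 3 (adjusted p up to 0.171). Col3a1 lost its call without low libraries 1 and 3 or high libraries 1, 2 and 3 (adjusted p up to 0.157). Lrat lost its call without low libraries 2 and 3 or high libraries 1 and 3 (adjusted p up to 0.13). Des lost its call without low libraries 2 and 3 (adjusted p up to 0.102).

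More male-biased liver genes rose than fell. Of 20 male-biased liver genes, 4 rose and 1 fell (9 rose and 1 fell adjusted over the list alone). Male-biased liver genes had a camera adjusted p of 4.4e-04, and adjusted p = 0.543 with an estimated correlation. Beside the fall of Elovl3, Ugt2b38 (ENSMUSG00000061906, 1.23 ± 0.16, adjusted p = 0.0027) and Cyp4a12a (ENSMUSG00000066071, 0.68 ± 0.14, adjusted p = 0.02) rose. Mup3 (ENSMUSG00000066154, 0.56 ± 0.13, adjusted p = 0.0435) rose. Of 23 unfolded protein response genes, 1 rose and 4 fell (1 rose and 6 fell adjusted over the list alone). Unfolded protein response genes had a camera adjusted p of 0.0271, and adjusted p = 0.688 with an estimated correlation. That camera call was lost without low libraries 1 and 3 or high library 1 (adjusted p up to 0.0994). Hspa5 (ENSMUSG00000026864), an endoplasmic reticulum chaperone, fell from 742 ± 102 to 376 ± 51.9 CPM (log2 fold change -0.98, SE 0.13, adjusted p = 0.00301). Trib3 (ENSMUSG00000032715, 1.15 ± 0.23, adjusted p = 0.0187) rose. Manf (ENSMUSG00000032575, -1.30 ± 0.26, adjusted p = 0.0306) and Creld2 (ENSMUSG00000023272, -0.99 ± 0.20, adjusted p = 0.0257) fell. Of 20 p53 targets, 1 rose and 1 fell (1 rose and 1 fell adjusted over the list alone). The p53 targets had a camera adjusted p of 0.975, and adjusted p = 0.974 with an estimated correlation. The p53 list median of 0.03 turned negative on the TPM scale, Ccng1 (ENSMUSG00000020326, 0.43 ± 0.09, adjusted p = 0.0244) rose and Cdkn1a fell. Cyp4a12a lost its call without low libraries 1 and 2 or high libraries 1 and 2 (adjusted p up to 0.0899). Mup3 lost its call without low library 3 or high libraries 1, 2 and 3 (adjusted p up to 0.167). Manf lost its call without low libraries 1 and 3 or high libraries 1, 2 and 3 (adjusted p up to 0.102). Creld2 lost its call without low libraries 1 and 3 or high libraries 1 and 2 (adjusted p up to 0.105). Trib3 lost its call without low library 1 or high libraries 1 and 2 (adjusted p up to 0.0686). Ccng1 lost its call without low libraries 1 and 3 or high libraries 1 and 2 (adjusted p up to 0.112).

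In the liver, Apc went from 31.1 ± 4.56 to 33.2 ± 5.25 CPM and did not pass (log2 fold change 0.10, SE 0.14, adjusted p = 0.748), with a sign that turned on the TPM scale. Cmah went from 233 ± 32 to 209 ± 21.5 CPM and did not pass (log2 fold change -0.16, SE 0.13, adjusted p = 0.514). Of 59 colorectal cancer pathway genes, 2 rose and 1 fell (2 rose and 1 fell adjusted over the list alone). That was below the 6.47% called over all liver genes. Colorectal cancer pathway genes had a camera adjusted p of 0.321, and adjusted p = 0.693 with an estimated correlation. Pik3r1 (ENSMUSG00000041417, 0.59 ± 0.14, adjusted p = 0.0406) and Tgfbr1 (ENSMUSG00000007613, 0.59 ± 0.12, adjusted p = 0.0186) rose. Rac2 (ENSMUSG00000033220, -1.09 ± 0.15, adjusted p = 0.00326) fell. Of 16 sialic acid genes, 2 rose and 2 fell (3 rose and 2 fell adjusted over the list alone). Sialic acid genes had a camera adjusted p of 0.63, and adjusted p = 0.71 with an estimated correlation. Neu3 fell from 3.87 ± 1.02 to 1.17 ± 0.157 CPM (log2 fold change -1.73, SE 0.23, adjusted p = 0.00307). Neu1 (ENSMUSG00000007038, 0.43 ± 0.09, adjusted p = 0.0225) and Amdhd2 (ENSMUSG00000036820, 0.60 ± 0.13, adjusted p = 0.0268) rose. Neu2 (ENSMUSG00000079434, -1.22 ± 0.31, adjusted p = 0.0488) fell. Of 14 sialyltransferase genes, 1 rose and 1 fell (1 rose and 1 fell adjusted over the list alone). Sialyltransferase genes had a camera adjusted p of 0.804, and adjusted p = 0.862 with an estimated correlation. St3gal5 (0.47 ± 0.12, adjusted p = 0.0449) rose. St3gal1 (-1.09 ± 0.12, adjusted p = 0.00121) fell. The medians of the colorectal cancer (0.03) and sialic acid (0.05) lists turned negative on the TPM scale. Pik3r1 lost its call without low libraries 1, 2 and 3 or high libraries 1 and 2 (adjusted p up to 0.163). Tgfbr1 lost its call without low libraries 1 and 3 or high libraries 1 and 2 (adjusted p up to 0.0859). Neu2 lost its call without low libraries 1 and 2 or high libraries 1, 2 and 3 (adjusted p up to 0.124). Neu1 lost its call without low libraries 1 and 3 or high library 2 (adjusted p up to 0.0846). Amdhd2 lost its call without low libraries 1 and 3 or high libraries 2 and 3 (adjusted p up to 0.107). St3gal5 lost its call without low libraries 1, 2 and 3 or high libraries 1 and 2 (adjusted p up to 0.173).

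By the same test, 1004 of 15522 genes differed in the liver (6.47%), 489 higher and 515 lower. Of these, 315 differed by at least 2-fold (190 higher, 125 lower). The biological coefficient of variation was 23.2%. Groups did not overlap for 4444 genes (28.6%, against 10% by chance), and 296 genes (150 higher, 146 lower) were called in every fit that left out 1 library. The count fell to 534 without low library 1, 387 without low library 3, 563 without high library 1 and 388 without high library 2. On log2(TPM + 1), limma called 113 genes higher and 1571 lower (6.71% higher, against 48.7%). The median log2 change over all genes was then -0.18, so directions in the liver are relative to the scaling used. The summed CPM of the 16 pancreatic acinar genes was 10261 in low library 1 and 4324 in high library 1, against 31.7 to 60.3 in the other liver libraries. Camera called 26 of 53 lists in the liver, 3 higher and 23 lower. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05. The fry test called 9 lists in 1 direction and 40 in either.

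The change from low to high Neu5Gc differed between the tissues for 1504 of 18703 genes (763 higher and 741 lower in the colorectum relative to the liver) in the interaction test of edgeR. The causes of these differences were not tested. The log2 change of Ppard was 0.27 in the colorectum and -2.79 in the liver (difference 3.08, SE 0.21, adjusted p = 3.1e-06). That of Clec2h was -0.33 and 2.61 (difference -2.93, SE 0.21, adjusted p = 3.1e-06). For Cmya5 (ENSMUSG00000047419) it was -0.86 and 5.38 (difference -6.25, SE 0.50, adjusted p = 8.8e-06). On log2(TPM + 1) the Cmya5 changes were only -0.08 and 0.43, so their size depends on the scale. Pitpnm1 had 0.22 and -1.79 (difference 2.01, SE 0.18, adjusted p = 3.2e-05). Neu3 rose in the colorectum and fell in the liver (difference 3.83, SE 0.37, adjusted p = 3.8e-05). The count of differing genes fell to 914 without liver low library 1, 825 without liver low library 3, 945 without liver high library 1 and 876 without liver high library 2. Of 15076 genes tested in both tissues, 21 rose in both (32.5 expected for independent lists, Fisher's exact p = 0.0331) and 52 fell in both (39.3 expected, exact p = 0.042). Another 46 rose in the colorectum and fell in the liver (36.1 expected, exact p = 0.0943), and 49 went the opposite way (35.4 expected, exact p = 0.0204). Genes are not independent in these exact tests, and their p-values were not adjusted for the number of overlaps compared.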

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

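Chance singles out a library in about 1 in 20 groups (5%), and 44 of 260 groups of values (16.9%) had a library far from the others of its group. Each test of an explanation below was chosen after the result was seen, and only for further skeletal muscle genes were the bounds set before their own values were read.

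In the colorectum the 2784 called genes include posterior and middle HOX genes, whose summed CPM in low library 3 (115 and 26.9) lay apart from the other low libraries. If the low and high libraries came from different stretches of the large bowel, low library 3 should also lie between the groups in other genes, and over non-HOX genes called without it its median place was 0.491 of the way to the high group, against 0.118, 0.0443 and 0.083 for low libraries 1, 2 and 4. A difference in the stretch sampled is therefore a candidate explanation, and an effect of the Neu5Gc dose stays open, as no label gives the position. Of the 2774 calls besides the 10 largest falls, 94.3% kept at least 50% of their log2 change without low libraries 3 and 4. Most of these log2 changes thus did not rest on those libraries, though only 1562 of all 2784 genes stayed called. Added kidney or pancreas transcripts there would mainly give falls, and 1309 of all 2784 calls were rises. The share was not taken over falls alone, so it cannot exclude such transcripts behind single falls, such as that of Slc2a2. For the 10 largest falls, for which these libraries were picked, it tests nothing. Of 100 splits of these libraries only the real one called as many genes (2784, highest other 5), which argues against chance.

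The 13 clock genes called in the liver had a median absolute log2 change of 2.89. If both tissues of the high mice had been taken at another hour, the same genes should move in the colorectum, where their median change in the liver's direction was 0.081 (standard error 0.22), and 10 of the 13 differed between tissues. That argues against this explanation only if clock genes follow the hour about as far in the colorectum as in the liver. The standard error treats the genes as independent, and no label says that both tissues came from the same mice. Unequal depth does not account for them either, as 13 were called with all liver libraries thinned to 1 depth. A different hour for the livers alone, or an effect of Neu5Gc on the liver clock, was not tested and stays open, for the other liver calls too.

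The skeletal muscle genes rose in the high liver libraries, and 13 of the called genes were called at equal depth, which argues against depth. Muscle tissue carried over into those libraries should raise at least 80% of further muscle genes 4-fold, and under 50% would argue against it. Of 23 such genes 69.6% (16) were higher by that much, between these bounds, with a median log2 change of 2.98 and 20 called higher. This cannot be told apart from a change within the liver, since Neb (-0.09, not called) averaged 36.6 CPM in the low livers, a baseline that would hide a small share of muscle RNA, while Ampd1 (-0.23) and Trim63 (0.84) were not called either.

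Among 10 splits of the liver libraries the real one called 1004 genes (highest other 1) and 26 lists (highest other 20), each reached by 1 split, too few splits for a share under 0.05. For the difference between tissues 1 of 100 splits reached 1504 genes (highest other 265, from a split that kept the colorectum groups). The splits redrew the groups in both tissues, so a group difference in 1 tissue alone could make the real split stand out. They therefore cannot exclude chance for the difference between tissues. For lists in the colorectum 33 of 100 splits called as many as the real 31 (highest other 35), so chance cannot be excluded.

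Colorectum low library 3 lay far above the others of its group in CPM for Ly6g 3.74, Cmah 99.8, Tcf7l1 24.1, St6galnac4 51.3, H2-DMb2 5.84, Tgm3 172, Pancreatic acinar cells (sum) 5768 and Posterior HOX genes (sum) 115. Colorectum low library 3 lay far below the others of its group in CPM for Slc10a2 12.6, Rps28 141, Rpl27a 110.1, Prap1 2.28, Hoxb8 3.68 and Middle HOX genes (sum) 26.9. Colorectum low library 1 lay far above the others of its group in CPM for Exosc6 2.61 and Rsad2 44.9, and far below them for H2-DMb1 10.2. Colorectum low library 4 lay far above the others of its group in CPM for Alb 739, Slc2a2 89.5, Slco1a1 96.6, Atp6v0a4 83, Tmem229a 80.4, Slc3a1 226 and Kidney tubule (sum) 15758. Colorectum low library 4 lay far below the others of its group in CPM for Map2k1 121. Colorectum low library 2 lay far above the others of its group in CPM for Spdef 171, and far below them for Flt1 31.4. Colorectum high library 4 lay far above the others of its group in CPM for Mettl7a3 22.6, Rac3 14.3, St3gal1 28.8, Tnf 14.1 and Paneth defensins and lysozyme (sum) 403. Colorectum high library 4 lay far below the others of its group in CPM for Casd1 101, mt-Nd2 641 and Prap1 0.0716. Colorectum high library 1 lay far above the others of its group in CPM for Acsm2 4.86, Slc7a13 0.845, Ggt1 4.29 and Kidney tubule (sum) 60.8. Colorectum high library 3 lay far above the others of its group in CPM for Kdr 35.3. Colorectum high library 2 lay far above the others of its group in CPM for mt-Nd4l 301, and far below them for Rpl12 41.1. Colorectum high library 6 lay far below the others of its group in CPM for Cmya5 0.368. Colorectum high library 5 lay far above the others of its group in CPM for Prostate and seminal vesicle (sum) 163.

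Changes from low to high Neu5Gc differed between tissues, by the interaction test, for 1504 genes, with log2 differences of 3.08 for Ppard, -2.93 for Clec2h, -6.25 for Cmya5 and 2.01 for Pitpnm1.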

How the results depend on the processing

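Alternatives chosen after seeing the data are named above, under data processing. The cause of each change below was not tested, except that the 2-fold threshold at an adjusted p calls fewer genes by construction. In the colorectum (2784 genes), 477 were called with the replicate number as a block, 1621 on log2(TPM + 1) (628 higher, 993 lower), 1616 on log2(TPM + 0.1), 1431 with no TPM filter, 1799 without low libraries 3 and 4 and high libraries 4 and 5, 1814 at an unadjusted p under 0.05 with at least 2-fold change, 1209 at an adjusted p with at least 2-fold, and 1592 to 3654 with 1 library left out. In the liver (1004), 1742 were called by the DESeq2 Wald test, 630 with the block, 446 with all 16 libraries in 1 fit, 1684 on log2(TPM + 1), 1688 on log2(TPM + 0.1), 591 and 315 at the unadjusted and adjusted 2-fold thresholds, and 387 to 935 with 1 library left out. For the difference (1504), the DESeq2 Wald test called 2352, the block 540, and fits with 1 library left out 825 to 2177. Without low libraries 3 and 4, 20 colorectum lists were called, of which 19 were among the 31. The fry test called 6 there and 9 in the liver (8 of them called by camera). With an estimated correlation camera called 0 in each tissue (2 and 3 lists at an unadjusted p under 0.05). Within 1.5 times were DESeq2 size factors (2735, 1009 and 1527 genes for colorectum, liver and difference), limma-voom (2647, 993 and 1045), no count filter (2166, 1080 and 1198), the fit without the robust step (2878 and 846), the DESeq2 Wald test in the colorectum (3765), the liver thinned to 1 depth (977, 925 of them shared) the liver without muscle and clock genes (967), and the liver with no TPM filter (724). The block called 28 and 31 lists. Signs turned without low libraries 3 and 4 and high libraries 4 and 5 for Slc2a2 (0.024), Akr1d1 (0.23) and the median of immunoglobulin variable segments (-0.19) in the colorectum. The camera direction of male-biased liver genes turned there too, while their median stayed negative (-0.21). Apc in the liver ran from -0.037 (without high library 1) to 0.219 with 1 library left out. Of 92 named liver genes, 2 turned sign on the TPM scale, Apc (-0.09) and Alb (-0.05).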

Other observations

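On principal components of the colorectum libraries, low library 3 stood at 93.9 and low library 4 at -59.8 on the second component, against 18.6 and 20.1 for low libraries 1 and 2. The 10 most abundant genes took 15.3% of counts in low library 3 and 5.55% to 8.39% in the other colorectum libraries, and 18.3% to 24.9% in the liver libraries.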
